A study of Homo sapiens with 8 samples.

How the data were processed

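RNA was measured by sequencing in 8 libraries of primary human bronchial epithelial cells, which are cells of the lining of the large airways grown in culture. Per the labels, 3 donors gave cells that were infected with a lentivirus carrying either DN-GRHL2, a mutant form of the transcription factor GRHL2, or H2B-GFP, a histone fused to a fluorescent protein that served as the control virus. Cells of 2 of these donors were also sequenced without infection. Per the labels' protocols, early-passage cells were infected at 40% confluence, puromycin was added 48 h later to select infected cells, and doxycycline was given for 24 h once the cultures were confluent. Whether the uninfected cultures received puromycin or doxycycline is not given in the sources used here. Per the labels' protocols, messenger RNA was taken from total RNA on oligo-dT beads, copied into complementary DNA with random primers, fragmented and tagged with a transposase, and sequenced on 1 instrument type from an equimolar pool. The kit as described does not mark the strand, so reads from overlapping genes on opposite strands could not be separated.

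The authors' deposited table holds raw counts for 40709 RefSeq transcripts in 8 libraries. Per the submitters' processing notes, CASAVA, Bowtie 0.12.8, DESeq 1.10.1 and the human genome build hg19 were used, with no role given for each tool. The counting tool, its settings and the treatment of reads that match several places are not given in the sources used here. Every deposited count was even, so each counted fragment appeared to add 2. Transcripts of 1 gene shared counts: among 4911 genes with enough counts and several transcripts, 54.5% had a first and second transcript whose totals lay within 10% of each other. Counts were therefore taken from 1 transcript per gene, the one with the highest total over all libraries. Genes with near-identical copies may share reads in such a table, and no coordinates are given because the reference used here for names (GRCh38.p14) is another build than that of the table.

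Gene names came from a RefSeq table, which matched 39320 transcripts, and from the GENCODE annotation, which matched 520 more. The 869 unmatched transcripts were left out, and the matched ones held 99.2% of all counts. Of 23526 genes, 101 linked to the Y chromosome or to X inactivation were left out to protect the donors, which left 23425. The totals over these genes ran from 23361960 counts in uninfected replicate 2 to 35965550 in H2B-GFP replicate 2. Rows for ribosomal RNA held between 2.65% and 4.01% of counts in 7 libraries and 7.15% in DN-GRHL2 replicate 3 (95% Wilson interval 7.14% to 7.16%). Such intervals cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules.

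Tests were run with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The main test was edgeR's quasi-likelihood test on the counts, with TMM library sizes, edgeR's default filter on low counts, all 8 libraries in 1 model of 3 group means, and Benjamini-Hochberg adjustment over the 15182 genes that passed the filter. The threshold was an adjusted p of 0.05. The model had 5 residual degrees of freedom and a common biological coefficient of variation of 0.305. A standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, a gene's count scaled to the library's TMM size, as mean ± SD.

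The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The 27 gene lists held 474 entries, and 471 were left after 3 that repeated a gene within its list were dropped. Of these, 457 were in the table. A gene could stand in more than 1 list, as GRHL1 did. Lists with at least 5 tested genes were compared with all other genes by limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. Camera with an estimated correlation and fry were run beside it. The fry calls counted here ask only whether the genes of a list move, on balance, 1 way. Its mixed test asks instead whether they move in any direction. For DN-GRHL2 against H2B-GFP, the named genes were the 12 largest rises and 12 largest falls past the threshold with a mean of at least 10 CPM in the higher group and the same direction in all 3 donor pairs. Places left open were filled by the same rule from the fit with the donor as a block. For each comparison with uninfected cells the rule took 6 rises and 6 falls. Up to 4 members of each list with the smallest p could also be named, and GRHL1, GRHL2 and GRHL3 always were. Some results for single genes are not reported here.

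The replicate number is the donor, per the labels, so libraries with the same number are paired by donor. In fits without the donor, each p-value rests on the spread between cultures of different donors. With the donor as a block it rests on the spread left after donor differences are taken out. The deviations of same-donor libraries from their group means correlated across genes at −0.12, 0.13 and 0.50 for H2B-GFP with DN-GRHL2, at 0.10 and 0.15 for uninfected with H2B-GFP, and at −0.22 and −0.22 for uninfected with DN-GRHL2. Between libraries of different donors, those for H2B-GFP with DN-GRHL2 ran from −0.44 to 0.39. Genes are not independent replicates in these correlations. Alternatives were the donor as a block, DESeq2, 2 other scalings, no filter and a stricter filter (1 CPM in at least 3 libraries and a total of at least 100), only the 2 groups compared, a robust spread, and each library and each donor left out in turn. Halved counts, summed transcripts, removal of ribosomal RNA rows, a threshold of 0.10 and the blocked set test with an estimated correlation were added after the data were seen. Leaving out 1 uninfected library leaves that group with 1 sample, which is then assumed to vary like the other groups.

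The procedure was tested on simulated counts with 15182 genes, of which 100 were changed 2-fold and 100 were changed 4-fold. For DN-GRHL2 against H2B-GFP it called 25% of the 2-fold and 93% of the 4-fold genes, with 3 false calls among 121. For H2B-GFP against uninfected cells it called 13% and 85%, with 11 false calls among 109, and for DN-GRHL2 against uninfected cells 13% and 85%, with 9 false calls among 107. In each comparison a simulated changed list was recovered and 0 of 20 unchanged lists were called. The changed genes had a mean of at least 5 CPM over all libraries, so the rates for 2-fold and 4-fold changes do not cover genes at lower levels. The simulated genes were drawn independently of each other and without donor effects. The list result thus does not show how camera behaves where genes of a list move together, as in the cell cycle list (estimated correlation 0.86).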

Results

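The data are RNA-seq counts from 8 libraries of cultured primary human bronchial epithelial cells: 2 uninfected, 3 infected with the control virus H2B-GFP and 3 infected with DN-GRHL2. The series title names grainyhead-like transcription factors in the human airway epithelium, and the design asks what the mutant GRHL2 changes relative to a control virus in cells of the same donors. Total counts over 1 transcript per gene were 31014122 and 23361960 in uninfected replicates 1 and 2. They were 29467818, 35965550 and 27461864 in H2B-GFP replicates 1 to 3, and 24555564, 29583922 and 28708126 in DN-GRHL2 replicates 1 to 3. The first principal component of log2 CPM, with 37.4% of the variance, placed the DN-GRHL2 libraries between 46.2 and 56.9. H2B-GFP replicates 1 and 3 lay at −50.9 and −39.4 and the uninfected libraries at −42.1 and −24.0, while H2B-GFP replicate 2 stood apart from its group at 1.31.

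GRHL2, the factor whose mutant form was expressed, was measured at 122 ± 16.9 CPM in DN-GRHL2 libraries (SD, n = 3), 101 ± 8.79 CPM in H2B-GFP libraries (SD, n = 3) and 99.6 ± 8.04 CPM in uninfected libraries (SD, n = 2). Its log2 difference between DN-GRHL2 and H2B-GFP was 0.28 ± 0.16 (SE) and did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.336), although it was higher in 3 of 3 donor pairs. Reads from the viral insert may be counted with the gene's own, so this value does not separate the 2 sources. GRHL1, another member of the family, was at 56.8 ± 4.87 CPM with DN-GRHL2 and 171 ± 46.5 CPM with H2B-GFP, lower in 3 of 3 pairs. Its log2 difference of −1.59 ± 0.22 missed the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0509) and passed with the donor as a block (adjusted p = 0.0429). GRHL3 was at 59.2 ± 11.6 and 36.7 ± 5.06 CPM, a log2 difference of 0.69 ± 0.20 that did not pass (edgeR adjusted p = 0.101), higher in 3 of 3 pairs. H2BC11, a histone H2B gene, was at 1355 ± 1014 CPM in H2B-GFP libraries against 1.06 ± 0.14 CPM in DN-GRHL2 and 0.574 ± 0.0675 CPM in uninfected libraries, and its counts may come from the H2B-GFP insert.

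**Figure D1:**
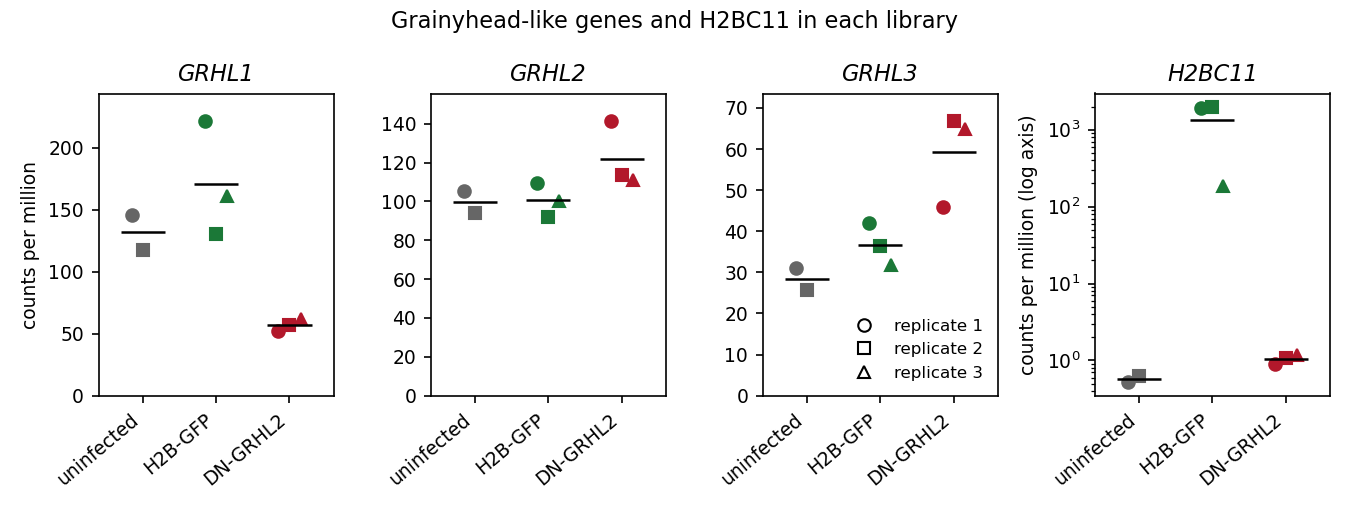
CPM of GRHL1, GRHL2, GRHL3 (linear axes from 0) and H2BC11 (log axis) in each of the 8 libraries, with 1 point per library, the marker giving the donor replicate and the bar the group mean. The DN-GRHL2 libraries have a GRHL1 mean of 56.8 CPM against 171 CPM in H2B-GFP libraries, and H2BC11 averages 1355 CPM in H2B-GFP against 1.06 CPM in DN-GRHL2 libraries.

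DN-GRHL2 against H2B-GFP is the main comparison. TPPP, a protein that promotes microtubule assembly, rose from 14.04 ± 2.42 to 50.3 ± 8.37 CPM (log2 1.84 ± 0.21; edgeR adjusted p = 0.0300). RNF150, a RING finger protein, rose from 2.70 ± 0.278 to 14.3 ± 3.77 CPM (log2 2.41 ± 0.26; edgeR adjusted p = 0.0281). GJB5, a connexin of gap junctions, fell from 94.99 ± 16.1 to 32.9 ± 3.96 CPM (log2 −1.53 ± 0.18; edgeR adjusted p = 0.0318). ANKRD22 fell from 20.4 ± 5.22 to 3.10 ± 0.0677 CPM (log2 −2.71 ± 0.25; edgeR adjusted p = 0.0103). H2BC11 was the remaining call (log2 −10.31 ± 0.96; edgeR adjusted p = 0.0103). Each of these 5 genes moved the same way in 3 of 3 donor pairs (n = 3 libraries per group). In total 5 of 15182 genes passed, 2 higher and 3 lower, and 3490 had an unadjusted p under 0.05. With the donor as a block 148 genes passed, 61 higher and 87 lower, and DESeq2 called 1314. At a threshold of 0.10, chosen after the data were seen, 973 passed.

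A further set of genes missed the threshold in this test and passed with the donor as a block, each in the same direction in 3 of 3 pairs. Higher with DN-GRHL2 were APCDD1, an inhibitor of Wnt signalling (log2 2.84 ± 0.59), PODXL, a sialomucin of apical membranes (log2 2.67 ± 0.46), and SBK1 (log2 2.42 ± 0.54). So were CYGB, or cytoglobin (log2 2.25 ± 0.31; 68.8 ± 27.0 against 14.5 ± 1.52 CPM), and GAS1 (log2 2.12 ± 0.68). PRR15 (log2 2.06 ± 0.51) and the interferon-induced antiviral gene RSAD2 (log2 2.02 ± 0.33) were higher. PHYHIP (log2 2.01 ± 0.45), TP53INP2 (log2 1.90 ± 0.43) and GRAMD1B (log2 1.86 ± 0.32) were also higher. Lower were SLC7A5, which imports large neutral amino acids (198 ± 34.1 against 2304 ± 1533 CPM; log2 −3.54 ± 0.49), and the secreted Wnt inhibitor SFRP1 (log2 −3.00 ± 0.39). G0S2, an inhibitor of lipolysis (log2 −2.49 ± 0.46), and the connexin GJB6 (log2 −2.49 ± 0.52) were lower. KCNJ5, a potassium channel subunit (log2 −2.45 ± 0.51), LARGE2 (log2 −2.32 ± 0.47), the bZIP factor JDP2 (log2 −2.27 ± 0.48) and RPL22L1 (log2 −2.06 ± 0.42) were lower as well. SLC7A5P2 (log2 −2.97 ± 0.46) is a pseudogene that may share reads with SLC7A5 and is uncertain for that reason. The blocked edgeR adjusted p of these genes ran from 0.0380 for LARGE2 to 0.0456 for SBK1. Their unblocked edgeR adjusted p ran from 0.0509 for SFRP1 to 0.127 for GAS1.

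Removal of 1 library changed the number of genes called between DN-GRHL2 and H2B-GFP. Without DN-GRHL2 replicate 1 or replicate 3, edgeR's quasi-likelihood test called 0 genes. At an unadjusted p under 0.05 there were 2880 and 2260, and DESeq2 on all libraries called 1314. Without DN-GRHL2 replicate 2 the edgeR test called 1 gene, which was not among the 5, so each of the 5 lost its call without any 1 of the DN-GRHL2 libraries. It called 2 (H2BC11 and ANKRD22) without H2B-GFP replicate 1 and 29 without H2B-GFP replicate 3. The count was 611 without H2B-GFP replicate 2, and 543 and 554 without uninfected replicates 1 and 2.

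**Figure D2:**
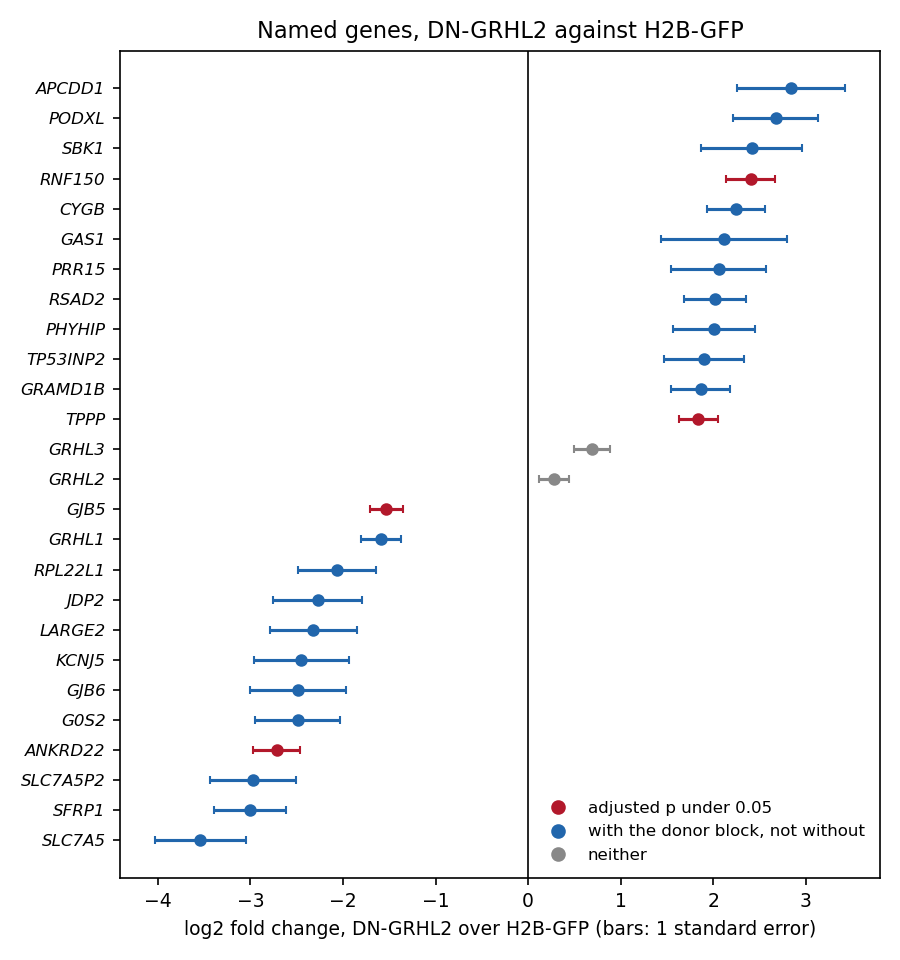
log2 fold change of DN-GRHL2 over H2B-GFP for the named genes (points) with 1 standard error (bars), coloured by whether the gene passed an adjusted p of 0.05, missed it but passed with the donor as a block, or passed in neither edgeR fit. H2BC11 lies outside the axis at −10.31 and is not drawn; GRHL1 is at −1.59, GRHL2 at 0.28 and GRHL3 at 0.69.

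Cell cycle genes were lower as a group with DN-GRHL2: all 22 tested members lay below 0, 19 of them in every donor pair, with a median log2 difference of −2.07 (camera adjusted p = 2e-05). The list's adjusted p = 0.603 with an estimated correlation. None of the 22 passed over all genes. When adjusted over the list alone 13 passed, and with the donor as a block 0 did. CCNB2, a mitotic cyclin, was at 11.998 ± 3.37 against 78.1 ± 38.1 CPM (log2 −2.70 ± 0.73; edgeR adjusted p = 0.0879). CENPF, a kinetochore protein, was at a log2 difference of −2.62 ± 0.72 and CDC20, an activator of the anaphase-promoting complex, at −2.66 ± 0.78. All 15 tested genes of the list for endoplasmic reticulum stress and amino acid responses also lay below 0, 9 of them in every donor pair, with a median of −1.30 (camera adjusted p = 1.6e-06). The list had an adjusted p = 0.603 with an estimated correlation. Of these genes, 12 passed when adjusted over the list alone. The chaperone HSP90B1, which passed with the donor as a block, was at 667 ± 187 against 1976 ± 193 CPM (log2 −1.57 ± 0.24; edgeR adjusted p = 0.0509, blocked 0.0429). PSAT1, an enzyme of serine synthesis, was at 40.4 ± 6.78 against 280 ± 188 CPM (log2 −2.79 ± 0.60), and the stress transcription factor XBP1 at a log2 difference of −1.30 ± 0.28. The list medians of the cell cycle genes, on log2 CPM centred per gene over all libraries, were −1.35, −0.42 and −0.89 in DN-GRHL2 replicates 1 to 3. They were 1.40, 0.28 and 1.64 in H2B-GFP replicates 1 to 3, and 1.64 and −2.14 in uninfected replicates 1 and 2. Those of the endoplasmic reticulum stress and amino acid genes were −1.07, −0.51 and −0.86 in DN-GRHL2 replicates 1 to 3 and 0.66, −0.34 and 0.55 in H2B-GFP replicates 1 to 3. H2B-GFP replicate 2, which stood apart on the first principal component, thus lay nearest to the DN-GRHL2 libraries.

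Genes of epithelial identity, of airway basal cells, and of migration and matrix remodelling were lower with DN-GRHL2. In the epithelial identity list 20 of 25 genes lay below 0 (median −0.36; camera adjusted p = 0.000932; adjusted p = 0.603 with an estimated correlation). Among them were LAD1 of the basement membrane zone (log2 −0.97 ± 0.17), the splicing factor ESRP2 (log2 −0.83 ± 0.16) and the transcription factor OVOL2 (log2 −1.14 ± 0.24). In the basal cell list 14 of 17 lay below 0 (median −0.63; camera adjusted p = 0.00162; adjusted p = 0.603 with an estimated correlation). The keratin KRT5 was at a log2 difference of −1.25 ± 0.27 and S100A2 at −1.17 ± 0.28. In the migration and matrix list 17 of 20 lay below 0 (median −0.66; camera adjusted p = 0.000865; adjusted p = 0.603 with an estimated correlation). The laminin chain LAMA3 was at −1.53 ± 0.27 and the integrin ITGB6 at −1.22 ± 0.28, both of which passed with the donor as a block (adjusted p = 0.0455 and 0.0429). In every donor pair 12 epithelial, 13 basal and 10 matrix genes were lower. None of these genes passed over all genes. Adjusted over the list alone, 9 lower and 1 higher gene of epithelial identity, 4 lower basal genes, and 9 lower and 1 higher matrix genes passed.

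Another 3 lists were lower as groups with DN-GRHL2. Of the adherens junction and desmosome genes 17 of 18 lay below 0 (median −0.46; camera adjusted p = 0.00665; adjusted p = 0.603 with an estimated correlation). The desmosomal cadherin DSC3 was at −1.15 ± 0.27 and the cadherin CDH3 at −0.79 ± 0.25, and 1 passed when adjusted over the list alone. Of the squamous and cornified envelope genes 18 of 25 lay below 0 (median −0.46; camera adjusted p = 0.0220; adjusted p = 0.603 with an estimated correlation). TGM1, a transglutaminase of the cornified envelope, was at −1.68 ± 0.27 and passed with the donor as a block (adjusted p = 0.0412). Adjusted over the list alone, 6 of these passed as lower and 1 as higher. Of the EGFR ligand and feedback genes 10 of 14 lay below 0 (median −0.73; camera adjusted p = 0.0330, blocked 0.0533; adjusted p = 0.603 with an estimated correlation). The ligand HBEGF was at −2.48 ± 0.47, and 7 lower and 1 higher passed when adjusted over the list alone. In every donor pair 12 junction, 11 squamous and 6 EGFR genes were lower. In donor 2 the centred EGFR list median was 0.068 with DN-GRHL2 against −0.051 with H2B-GFP, the opposite direction. The squamous median in donor 2 was −0.205 with DN-GRHL2 against −0.230 with H2B-GFP, so it was not lower there either. Without H2B-GFP replicate 1 the camera adjusted p was 0.0755 for the junction list, 0.0960 for the squamous list and 0.0960 for the EGFR list. The EGFR list was at 0.156 without DN-GRHL2 replicate 1 and 0.0505 without DN-GRHL2 replicate 3.

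Interferon response genes were higher as a group with DN-GRHL2: 21 of 24 lay above 0 and 17 were higher in every donor pair. The median log2 difference was 1.06 (camera adjusted p = 1.6e-06; adjusted p = 0.603 with an estimated correlation). None passed over all genes, 2 passed with the donor as a block and 12 when adjusted over the list alone. The antiviral GTPase gene MX2 was at 8.93 ± 3.86 against 1.94 ± 0.536 CPM (log2 2.20 ± 0.47; edgeR adjusted p = 0.0628, blocked 0.0429). RSAD2 was at 17.1 ± 4.58 against 4.23 ± 1.61 CPM, and IFIT3 at a log2 difference of 1.65 ± 0.36. Rows for ribosomal RNA, which an oligo-dT selection should lower, held 7.15% of counts in DN-GRHL2 replicate 3 and 2.65% to 4.01% in the other 7 libraries. These rows can share reads, so the values may overstate the ribosomal fraction.

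Tight junction and apical polarity genes lay above 0 in 16 of 21 cases (median 0.37; camera adjusted p = 0.0395; adjusted p = 0.603 with an estimated correlation). CLDN4, a claudin, was at 625 ± 421 against 185 ± 65.9 CPM (log2 1.76 ± 0.58; edgeR adjusted p = 0.130) and the polarity gene CRB3 at a log2 difference of 0.82 ± 0.27. Secretory and goblet cell genes lay above 0 in 13 of 18 cases (median 0.32; camera adjusted p = 0.0220; adjusted p = 0.643 with an estimated correlation). The centred secretory median was 0.18 in DN-GRHL2 replicate 3 against 0.45 in H2B-GFP replicate 3, the opposite direction. The mucin MUC16 was at a log2 difference of 1.26 ± 0.45 and MUC4 at 1.72 ± 0.91. Endothelial markers lay above 0 in 5 of 5 cases (median 0.78; camera adjusted p = 0.0395; adjusted p = 0.603 with an estimated correlation), at low levels. KDR, a VEGF receptor, was at 4.86 ± 0.673 against 0.757 ± 0.357 CPM (log2 2.67 ± 0.45; edgeR adjusted p = 0.0509, blocked 0.0485). In every donor pair 9 junction, 6 secretory and 3 endothelial genes were higher. None of these genes passed over all genes, and 1, KDR, passed when adjusted over the list alone. With the donor as a block 4 junction and 1 secretory gene also passed over the list alone. Without H2B-GFP replicate 1 the camera adjusted p was 0.0755 for tight junctions, 0.198 for secretory genes and 0.0755 for endothelial markers. It was 0.0795, 0.162 and 0.155 without H2B-GFP replicate 2, and without DN-GRHL2 replicate 2 it was 0.254 for tight junctions. The endothelial list, with 5 of 10 listed genes tested, had too few for camera without DN-GRHL2 replicate 2 or replicate 3.

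The other lists were not called between DN-GRHL2 and H2B-GFP. The mesenchymal transition list had 15 of 18 genes below 0 (median −0.40; camera adjusted p = 0.0706) and was called with the donor as a block (adjusted p = 0.0151). With the block and an estimated correlation the list's camera adjusted p was 0.406. Its transcription factor SNAI2 was at a log2 difference of −1.10 ± 0.21 (edgeR adjusted p = 0.0554, blocked 0.0429). The list had an adjusted p = 0.603 with an estimated correlation. Without H2B-GFP replicate 3 the camera adjusted p was 0.00677 for it, 0.0206 for inflammatory cytokines and 0.00463 for YAP and TAZ targets. It was 0.0254 for the mesenchymal list and 0.0332 for cholesterol synthesis without DN-GRHL2 replicate 1. It was 6.3e-05 for cytokines and 0.0122 for YAP and TAZ targets without DN-GRHL2 replicate 2. On all libraries the camera adjusted p was 0.0677 for inflammatory cytokines, among them IL1B (log2 −2.82 ± 0.61), and 0.0984 for YAP and TAZ targets. It was 0.195 for cholesterol synthesis and 0.244 for p53 targets, whose member CDKN1A was at 1.07 ± 0.28. It was 0.394 for immediate-early and heat shock genes, 0.394 for the oxidative stress response, and 0.507 for ciliated cell genes. The value was 0.507 for immune cell markers and 0.57 for the Notch pathway, where the ligand JAG1 was at −1.65 ± 0.34 (edgeR adjusted p = 0.0615, blocked 0.0456). The H2B histone list (camera adjusted p = 0.507) had a median of 0.17 and a mean of −0.91, with H2BC11 at −10.31. Fibroblast markers (camera adjusted p = 0.786) had a median of −0.015 and a mean of 0.44, with camera's direction upward. No gene passed over all genes among the 3 tested genes of the GRHL family list, the 4 of the neuroendocrine and ionocyte list and the 4 of the RNA quality list (RN7SK, RN7SL1, MALAT1 and NEAT1), which were too few for camera. GRHL1 and GRHL3 of the first, 0 genes of the neuroendocrine and ionocyte list and RN7SK (log2 2.41 ± 0.38) of the RNA quality list passed when adjusted over the list alone.

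**Figure D3:**
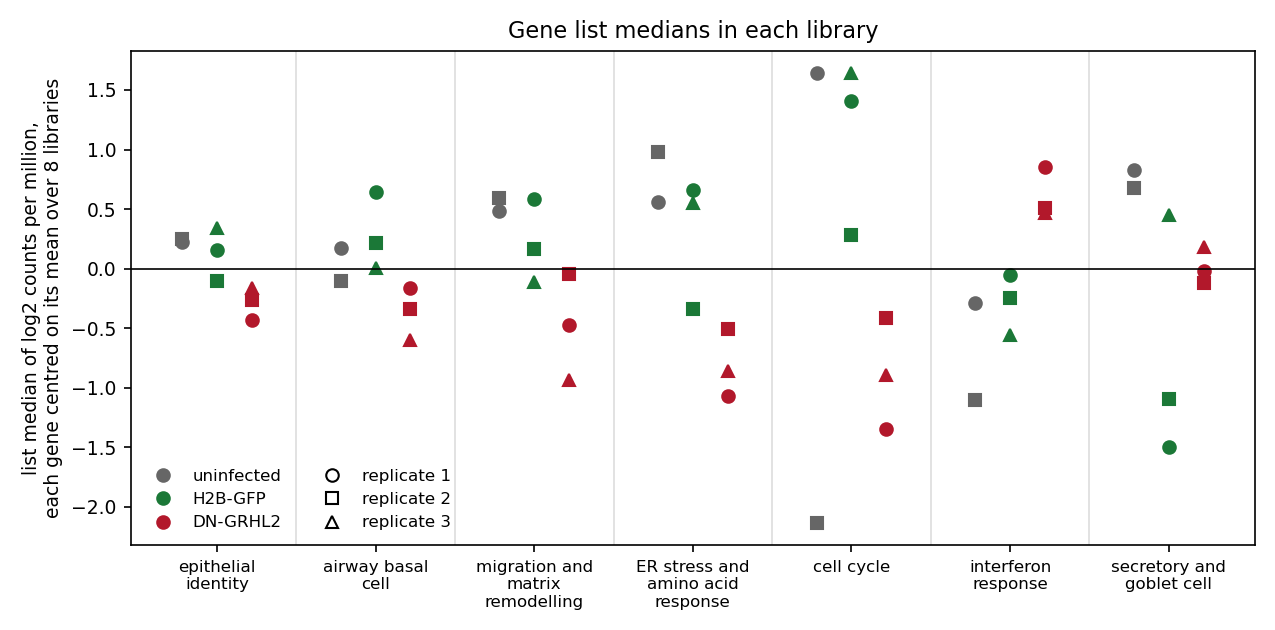
Median, over the genes of 7 lists, of log2 CPM centred on each gene's mean over the 8 libraries (y axis), with 1 point per library, colour for the group and marker for the donor replicate. The interferon medians are 0.85, 0.51 and 0.46 in the DN-GRHL2 libraries, and the cell cycle median of uninfected replicate 2 is −2.14.

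H2B-GFP against uninfected cells measures what infection with the control virus, its insert and its selection go with. Puromycin and doxycycline are part of this difference if the uninfected cultures did not receive them, and donor 3 is in the H2B-GFP group only. Secretory and goblet cell genes were lower in H2B-GFP libraries: 16 of 18 lay below 0 and 17 were lower in both donor pairs, a tally that H2B-GFP replicate 3 does not enter. The median log2 difference was −0.88 (camera adjusted p = 5.4e-12; adjusted p = 0.403 with an estimated correlation). The centred list medians were −1.49 and −1.10 in H2B-GFP replicates 1 and 2, but 0.45 in replicate 3, close to 0.82 and 0.68 in the uninfected libraries. LCN2, or lipocalin 2, was at 156 ± 59.8 CPM (SD, n = 3) against 374 ± 8.94 CPM (SD, n = 2; log2 −1.26 ± 0.32). PIGR, the transporter of polymeric immunoglobulins, was at 3.08 ± 4.11 against 21.6 ± 1.32 CPM (log2 −2.81 ± 0.89). Both had an edgeR adjusted p of 0.998. Adjusted over the list alone, 6 secretory genes passed, and 11 with the donor as a block. H2B histone genes lay above 0 in 6 of 8 cases (median 0.83; camera adjusted p = 0.000971; adjusted p = 0.403 with an estimated correlation). Their member H2BC11, whose counts may come from the H2B-GFP insert, was at a log2 difference of 11.20 ± 1.22 (edgeR adjusted p = 0.0813). The list's mean was 2.20 with it, and the list was not tested without it. The call may thus partly reflect the insert. The direction of the cell cycle list turned on 1 uninfected library. With all libraries 21 of 22 genes lay above 0 (median 0.41; camera adjusted p = 5.8e-05; adjusted p = 0.780 with an estimated correlation), but 3 were higher in both donor pairs. Without uninfected replicate 2 the list was called as lower (median −0.49; camera adjusted p = 0.0012), and without uninfected replicate 1 as higher (median 3.42; camera adjusted p = 4.3e-23). Over the list alone, 0 cell cycle genes and 1 histone gene passed. GRHL1 (log2 0.38 ± 0.24), GRHL2 (log2 0.01 ± 0.18) and GRHL3 (log2 0.37 ± 0.22) did not pass.

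No single gene passed between H2B-GFP and uninfected cells in edgeR's quasi-likelihood test (0 of 15182). Of these, 585 (3.85%) had an unadjusted p under 0.05, the smallest adjusted p was 0.0813, and DESeq2 called 7. That share lies below the 0.05 that would fall there if no gene differed, while between DN-GRHL2 and H2B-GFP it was 23.0%. With the donor as a block the count of genes passing was also 0, with 1171 genes (7.71%) at an unadjusted p under 0.05. Without H2B-GFP replicate 3 the main test called 6.

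A further 6 lists were called between H2B-GFP and uninfected cells, and each lost its call without at least 1 library. Lower in H2B-GFP were immune cell markers (camera adjusted p = 0.0117; 7 of 8 below 0), migration and matrix genes (0.0117; blocked 0.315; 16 of 20 below 0), p53 targets (0.0254; 14 of 17 below 0) and endoplasmic reticulum stress and amino acid genes (0.0370; blocked 0.0856; 11 of 15 below 0). Immune markers had an adjusted p = 0.403 with an estimated correlation and the other 3 lists an adjusted p = 0.780. Higher were interferon response genes (0.0244; 18 of 24 above 0; median 0.26) and cholesterol synthesis genes (0.0409; 14 of 15 above 0). Both had an adjusted p = 0.780 with an estimated correlation. Of the genes of these 6 lists 0 passed when adjusted over the list alone, and with the donor as a block 1 interferon gene, 1 p53 target and 1 immune marker did. Without uninfected replicate 1 the camera adjusted p was 0.0727 for immune markers and for matrix genes. Without uninfected replicate 2 it was 0.102 for matrix genes, 0.855 for amino acid genes and 0.999 for p53 targets, interferon and cholesterol genes, with the direction turned for p53 targets and cholesterol. Without H2B-GFP replicate 1 it was 0.159 for p53 targets and 0.15 for interferon genes. Without replicate 2 it was 0.0521 for matrix, 0.738 for amino acid and 0.508 for cholesterol genes. Without replicate 3 it was 0.471 for matrix genes and 0.0516 for p53 targets. Without DN-GRHL2 replicate 3 it was 0.0511 for amino acid and 0.0524 for cholesterol genes.

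Lists not called between H2B-GFP and uninfected cells included epithelial identity (camera adjusted p = 0.187), which was called as lower with the donor as a block (adjusted p = 0.0466). With the block and an estimated correlation its camera adjusted p was 0.621. The camera adjusted p was 0.104 for the Notch pathway, 0.164 for immediate-early genes, 0.187 for EGFR ligands, 0.187 for fibroblast markers, 0.319 for tight junctions, 0.353 for the basal cell list, 0.353 for the mesenchymal list and 0.396 for squamous genes. It was 0.57 for endothelial markers, 0.582 for YAP and TAZ targets, 0.610 for ciliated cells, 0.667 for oxidative stress, 0.996 for cytokines and 0.996 for adherens junctions. Fibroblast markers had a median of 0.17 and a mean of −0.087 with camera's direction downward, and their member POSTN, a matrix protein, was at 1.02 ± 0.633 against 18.0 ± 6.05 CPM (log2 −4.13 ± 0.69; edgeR adjusted p = 0.998). Oxidative stress genes (median 0.024, mean −0.014), cytokines (median −0.0096, mean 0.092) and adherens junctions (median 0.062 with camera's direction downward) also differed in sign between measures. Camera called EGFR ligands (adjusted p = 0.0280) and immediate-early genes (adjusted p = 0.00417) without uninfected replicate 1, and EGFR ligands (adjusted p = 0.0230), mesenchymal (adjusted p = 0.0258) and Notch genes (adjusted p = 0.00743) without H2B-GFP replicate 1. It called immediate-early and squamous genes without H2B-GFP replicate 2 (adjusted p = 0.0397 each).

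DN-GRHL2 against uninfected cells combines the mutant factor with infection and, if the uninfected cultures lacked them, with puromycin and doxycycline. Donor 3 is in the DN-GRHL2 group only. The comparison shares libraries with both other comparisons, so its calls are no independent repeat of them. The hyaluronan-binding protein gene CEMIP rose from 27.9 ± 17.6 CPM (SD, n = 2) to 281 ± 38.9 CPM (SD, n = 3; log2 3.33 ± 0.64; edgeR adjusted p = 0.0491). IFIT2 of the interferon response rose from 6.83 ± 2.998 to 47.9 ± 9.70 CPM (log2 2.80 ± 0.46; edgeR adjusted p = 0.0490). The histone gene H2BC12 rose from 13.5 ± 0.473 to 75.0 ± 5.84 CPM (log2 2.47 ± 0.39; edgeR adjusted p = 0.0490). Reads of near-identical H2B genes may be shared, so this value is uncertain. ARNT2 (log2 2.34 ± 0.42), RSAD2 (log2 2.25 ± 0.39) and RNF150 (log2 2.18 ± 0.31) rose as well. SLC7A5 fell from 2749 ± 1262 to 198 ± 34.1 CPM (log2 −3.80 ± 0.52; edgeR adjusted p = 0.0490). The serine synthesis genes PHGDH (log2 −3.71 ± 0.63; 279 ± 102 to 21.2 ± 3.66 CPM) and PSAT1 (log2 −3.37 ± 0.65) fell too. So did G0S2 (log2 −3.11 ± 0.49), the protease inhibitor SERPINA3 (log2 −3.04 ± 0.55) and SLC7A5P2 (log2 −3.02 ± 0.49), which may share reads with SLC7A5. GRHL1 fell as well (log2 −1.21 ± 0.23; edgeR adjusted p = 0.0491), GRHL2 was at 0.29 ± 0.18 (edgeR adjusted p = 0.354) and GRHL3 at 1.06 ± 0.23 (edgeR adjusted p = 0.0578). Each of the genes that rose or fell here did so in 2 of 2 donor pairs and lost its call with the donor as a block, for example SLC7A5 (blocked edgeR adjusted p = 0.0554), CEMIP (0.0584) and GRHL1 (0.0591).

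In edgeR's quasi-likelihood test 159 of 15182 genes passed between DN-GRHL2 and uninfected cells, 33 higher and 126 lower, with 3654 at an unadjusted p under 0.05. With the donor as a block 1 gene passed, PYCARD, an inflammasome adaptor noted only after its values were seen, which was lower (log2 −2.53 ± 0.20; blocked edgeR adjusted p = 0.0494). None of the genes said to have risen or fallen against uninfected cells passed with the block. RLE and upper-quartile scaling gave 0 (3643 and 3667 at an unadjusted p under 0.05). DESeq2 called 1524, of which 673 were higher. Among calls within the 15182 genes of the edgeR test, 44.1% were higher in DESeq2 and 20.8% in edgeR. Without 1 of uninfected replicates 1 and 2, H2B-GFP replicate 1 or DN-GRHL2 replicates 1, 2 and 3, edgeR called 0 genes. These fits had 2846, 2821, 3440, 3095, 2992 and 2743 genes at an unadjusted p under 0.05. The test called 632 without H2B-GFP replicate 2 and 298 without H2B-GFP replicate 3.

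Interferon response genes lay above 0 in 22 of 24 cases between DN-GRHL2 and uninfected cells (median 1.17; camera adjusted p = 7.2e-08; adjusted p = 0.538 with an estimated correlation). IFIT2, OASL (log2 2.23 ± 0.39) and RSAD2 passed over all genes and 14 when adjusted over the list alone. The genes of endoplasmic reticulum stress and amino acid responses lay below 0 in 15 of 15 cases (median −1.43; camera adjusted p = 7.2e-08; adjusted p = 0.538 with an estimated correlation). HSP90B1 (log2 −1.53 ± 0.26), XBP1 (log2 −1.63 ± 0.30) and PSAT1 passed and 12 when adjusted over the list alone. Epithelial identity (21 of 25 below 0; median −0.60; camera adjusted p = 3.9e-05), migration and matrix (17 of 20 below 0; median −1.19; camera adjusted p = 1.2e-05) and secretory genes (15 of 18 below 0; median −0.79; camera adjusted p = 0.0195) were lower. Epithelial identity had an adjusted p = 0.538 with an estimated correlation, and the other 2 lists an adjusted p = 0.540. Over all genes 1 gene of epithelial identity (GRHL1), 2 matrix genes and 0 secretory genes passed, all lower. Adjusted over the list alone, 10, 11 and 5 lower and 1, 1 and 1 higher genes passed, and with the donor as a block 9 secretory genes were lower.

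A further 7 lists were called between DN-GRHL2 and uninfected cells and lost the call without at least 1 library. Lower were EGFR ligands (camera adjusted p = 0.0103), where HBEGF fell (log2 −2.92 ± 0.50), and adherens junctions (0.0195; blocked 0.137), both with an adjusted p = 0.540 with an estimated correlation. Also lower were basal cell genes (0.0195) and mesenchymal genes (0.0303), where 2 genes fell, SNAI2 (log2 −1.22 ± 0.23) among them. These lists too had an adjusted p = 0.540 with an estimated correlation. Higher were H2B histone genes (0.0125), where H2BC12 rose, cholesterol synthesis (0.0195) and endothelial markers (0.0195). The higher lists had an adjusted p = 0.540 with an estimated correlation as well. Adjusted over the list alone, 2 EGFR, 5 junction, 2 basal and 4 mesenchymal genes passed as lower, and 1 mesenchymal, 2 histone, 0 cholesterol and 2 endothelial genes as higher. With the donor as a block 1 EGFR, 1 basal and 0 endothelial genes passed. Without uninfected replicate 2 the camera adjusted p was 0.104 for EGFR ligands, 0.119 for junctions and 0.10 for mesenchymal genes. It was 0.0770 for histone, 0.312 for cholesterol and 0.0887 for endothelial genes. Without uninfected replicate 1 it was 0.117 for basal and 0.135 for mesenchymal genes. Without DN-GRHL2 replicate 2 it was 0.0649 for basal and 0.0811 for cholesterol genes. Without DN-GRHL2 replicate 3 it was 0.0667 for junctions, 0.0556 for basal and 0.0879 for mesenchymal genes.

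The cell cycle list was not called between DN-GRHL2 and uninfected cells (22 of 22 below 0; median −1.50; camera adjusted p = 0.143), and its call turned on the uninfected libraries: it was called as lower without uninfected replicate 2 (adjusted p = 2.3e-13) and as higher without uninfected replicate 1 (adjusted p = 6.1e-05). Also not called by camera were cytokines (adjusted p = 0.119), squamous genes (0.122), and the Notch pathway (0.122). The same held for immediate-early genes (0.145), where EGR1 fell (log2 −1.17 ± 0.22; edgeR adjusted p = 0.0490), for tight junctions (0.193), immune markers (0.193) and fibroblast markers (0.228), where SFRP1 fell (log2 −2.05 ± 0.40; edgeR adjusted p = 0.0497). The fibroblast list had a median of −0.50 and a mean of 0.35. YAP and TAZ targets (0.256), ciliated cell genes (0.376), oxidative stress (0.536) and p53 targets (0.682) were not called either. Immediate-early genes were called without uninfected replicate 1 (adjusted p = 0.00758) and without DN-GRHL2 replicate 2 (0.0482), as were YAP and TAZ targets (0.0482) without the latter. Cytokines were called without uninfected replicate 2 (0.0303) and without DN-GRHL2 replicate 2 (0.000553), and tight junctions without DN-GRHL2 replicate 1 (0.0226).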

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

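The threshold of 0.10, halved counts, summed transcripts, removal of ribosomal RNA rows and the blocked set test with an estimated correlation were chosen after the data were seen; the other alternatives were planned. For DN-GRHL2 against H2B-GFP, where 5 genes passed, the replicate block (donor) gave 148, DESeq2 1314, no filter 414, the 2 groups alone 555, the paired fit of the 2 groups 934, a robust spread 94, halved counts 47, summed transcripts 47 and a threshold of 0.10 973. The 5 genes passed in each of these fits and in those with RLE scaling, a stricter filter or no ribosomal RNA rows, and 4 of them with upper-quartile scaling. With 1 library or donor left out the count ran from 0 to 879. For H2B-GFP against uninfected cells, where 0 passed in edgeR (585 at an unadjusted p under 0.05), DESeq2 gave 7, no filter 1, the paired fit of the 2 groups 2 and a threshold of 0.10 1, and the range with a library or donor left out was 0 to 6. For DN-GRHL2 against uninfected cells, where 159 passed, the replicate block gave 1, the paired fit of the 2 groups 0 (2244 at an unadjusted p under 0.05), RLE scaling 0, upper-quartile scaling 0, DESeq2 1524, no filter 483, the 2 groups alone 507 and a threshold of 0.10 1307, and the range was 0 to 632. The cause was not tested.

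Of the gene lists, 12, 9 and 12 were called in the 3 comparisons by camera at the preset correlation. With an estimated correlation, with fry's test for 1 direction, and with the replicate block and an estimated correlation, 0 were called in each. The smallest adjusted p with an estimated correlation was 0.603, 0.403 and 0.538, and by that fry test 0.102, 0.373 and 0.0506. Between DN-GRHL2 and H2B-GFP, fry's mixed test put some lists under 0.05, such as epithelial identity (adjusted p = 0.0014) and the Notch pathway (0.0016). Others, such as cell cycle genes (0.181), stayed above it. The mixed test asks for no shared direction, so it does not bear on lists given as higher or lower. With 1 library left out the number of lists ran from 6 to 15, from 4 to 10 and from 8 to 13. Apart from the calls given with the results, the donor block changed no other camera call of a list and no other call over all genes of a gene named here.

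Among 1035 values of 45 gene and comparison pairs under the alternatives, 644 kept their direction and side of the threshold, 192 lost the threshold, 192 gained it and 7 changed sign. The 7 were GRHL2 between H2B-GFP and uninfected cells, at 0.01 ± 0.18 in the main result: −0.0020 with DESeq2, −0.0020 with RLE scaling, −0.0035 with upper-quartile scaling, −0.019 with the paired fit of the 2 groups (replicate block), −0.069 without uninfected replicate 2, −0.051 without H2B-GFP replicate 1 and −0.0043 without donor 2. Depth ran from 23361960 to 35965550 counts. In simulated data at this depth and spread, 25% of 2-fold and 93% of 4-fold changes between DN-GRHL2 and H2B-GFP were called. The changed genes there had a mean of at least 5 CPM and no donor effects. In the real data, named genes with a fitted difference beyond 4-fold, such as SLC7A5 and SFRP1, missed the threshold. An uncalled gene thus need not have changed less than 4-fold.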

Other observations

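The tests of explanations, the set of histone genes and the splits of the libraries in this part were chosen after the results were seen, while the edgeR and DESeq2 calls were planned. Replication-dependent histone genes encode the histones made in S phase, and their transcripts usually end in a stem-loop without a poly(A) tail. The counts do not show whether the reads here came from transcripts with or without such a tail. H2BC11 (log2 −10.31 ± 0.96; edgeR adjusted p = 0.0103), whose counts can include the H2B-GFP insert, was left out. Of 18 other such genes with a mean of at least 1 CPM over all 8 libraries, 17 lay above 0 between DN-GRHL2 and H2B-GFP and 13 were higher in all 3 donor pairs, with a median log2 difference of 1.52. None of them passed in edgeR's quasi-likelihood test (0 of 18; 3490 genes in all at an unadjusted p under 0.05; DESeq2 called 1314 genes in all), and the set, picked for its values, was not tested as a group. The list of H2B histone genes fixed earlier was not called (camera adjusted p = 0.507). H2BC12 was at 75.0 against 24.4 CPM (log2 1.62 ± 0.32; edgeR adjusted p = 0.0587), H2AC6 at 30.8 against 9.07 CPM (log2 1.76 ± 0.34; edgeR adjusted p = 0.0561) and H1-2 at 36.4 against 13.1 CPM (log2 1.47 ± 0.42; edgeR adjusted p = 0.10). The small nuclear RNA RN7SK, a regulator of transcription elongation, was at 14.6 against 2.74 CPM (log2 2.41 ± 0.38; edgeR adjusted p = 0.0509).

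For the histone genes, carry-over of RNA without a poly(A) tail would raise other such RNAs by a like amount. The median log2 difference over 6 of them with a mean of at least 5 CPM over all libraries was 0.45, and 4 of the 6 had an upper limit of 2 standard errors below the histone median, while RN7SK (log2 2.41 ± 0.38) and RNA18SN5 (log2 1.12 ± 0.63) did not. Since copies share reads, the 6 are 3 kinds (ribosomal RNA, 7SL and RN7SK) that went apart, so carry-over and an effect of the mutant factor, an untested hypothesis, cannot be told apart. More cells in S phase would raise cell cycle genes if more cells were cycling. Their median was −2.07 and stayed between −2.38 and −1.81 with each library left out, which argues against more cycling cells. The list was not split by phase, and its named members include the mitotic cyclin CCNB2. It therefore cannot tell whether more cells were held in S phase. H2B genes may share reads with the H2B-GFP insert, which adds to their H2B-GFP counts.

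For the interferon genes, the DN-GRHL2 and H2B-GFP cultures were infected and selected alike per the labels, so the design sets no difference in infection between them. The centred list median of H2B-GFP lay above that of uninfected cells by 0.23 in donor 1 and 0.85 in donor 2, and DN-GRHL2 lay above H2B-GFP by 0.91, 0.75 and 1.02 in donors 1 to 3, so in donor 2 the step with the control virus was not the smaller one. More viral RNA in the DN-GRHL2 libraries stays open. GRHL2, whose counts may include the DN-GRHL2 insert, differed by 0.28 ± 0.16. The H2B-GFP libraries carry an insert of their own, so this value does not compare viral RNA between the groups. H2BC11, whose counts may include the H2B-GFP insert, was higher in the H2B-GFP libraries, and the reads of neither insert were counted apart. An effect of the mutant factor itself is the untested biological explanation.

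For the lower cell cycle genes, a growth state that also varies without DN-GRHL2 stays open, on 1 library from outside the comparison. Uninfected replicate 2, at a list median of −2.14, lay 1.72 log2 units under the highest DN-GRHL2 library (lowest minus highest −1.72). The H2B-GFP libraries, at 1.40, 0.28 and 1.64, all lay above the highest DN-GRHL2 library at −0.42. Uninfected replicate 2 did not share the low amino acid list of the DN-GRHL2 libraries, since its median there was 0.98. For the amino acid genes the same test left the question open, since the lowest library without DN-GRHL2 lay only 0.18 above the highest with it, less than the range of 0.56 among the DN-GRHL2 libraries, and it was H2B-GFP replicate 2 at −0.34, with the next at 0.55. A biological effect of the mutant factor on both groups was not tested.

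The 6 infected libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5 genes and the highest of the others 1, so 1 of 10 splits gave as many, and among the 4 splits that part all 3 donor pairs the highest other called 0 (the other splits part 1 pair). At a threshold of 0.10 the real split called 973 genes and the highest other 10. For the gene lists 2 of 10 splits called as many: another split, which parts 1 donor pair, also called 12 lists, and the highest other among those that part all pairs called 10. The number of lists called at the preset correlation therefore does not set the real split apart. Only the number of lists was compared, not which lists. In every other split each side holds 2 libraries of 1 group and 1 of the other, so it keeps part of the real difference. The other splits thus do not show what would be called without any difference. The 5 genes of the real split include H2BC11, whose counts may come from the H2B-GFP insert.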
